A study of Arabidopsis thaliana with 625 samples.

How the data were processed

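Single cells from the aerial tissue of Arabidopsis thaliana seedlings, collected 10 days after germination, were profiled with Smart-seq2, a plate-based full-length method without molecular identifiers, followed by a scaled-down Nextera XT library preparation, per the labels' protocols. The labels gave 2 reporter lines, ATML1p::YFP-RCI2A, a fluorescent membrane marker driven by an epidermal promoter, and TMMp::TMM-YFP, a fluorescent fusion of a stomatal-lineage receptor, with 2 pools for each line. Each deposited Smart-seq2 sample was 1 cell, so the pool was taken as the replicate and the sort plate, read from the cell names, as the smaller unit. Nothing in the sources used here said whether the pools came from separate cultures of plants or whether plates of 1 pool shared plants, so the p-values over pools or plates measured only the spread between them, which may be technical. Each plate held cells of 1 line, so plate and line could not be separated. Another 4 samples of the series, made with a 10X droplet method, were not analysed here.

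The deposited expression values were TPM per gene and cell, per the file headers, with totals between 999558.6 and 1000086.3 per cell. The program that quantified the Smart-seq2 reads was not given in the sources used here. The submitters' processing notes named Cell Ranger and the TAIR10 genome without saying which samples they applied to. The sort table held log2 values of 7 scatter and fluorescence channels per cell, deposited by the authors as log2 of the sorter's median signal in its gate, per the file headers. The FITC area was used as reporter brightness, the channel that reads YFP. TPM keep no read depth, so the number of genes at a TPM of at least 1 stood in for depth, and binomial intervals covered the counting of cells only. Library size and sampling noise per gene were unknown, and an exact 0 could be a failed capture. No cells were removed, no doublet caller was run because there were no counts, and no pair of cells had identical values. Gene names came from the TAIR10.1 reference annotation, which held 32548 of the 32833 genes in the table; the builds differed in name, so no coordinates are given. Reads of near-identical gene copies, such as LHCB1.1, LHCB1.2 and LHCB1.3, the RBCS genes and the histone genes, could have been split between copies, and values of their single members are uncertain.

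The choices named here were made before the data were examined unless stated otherwise. For the difference between lines, the mean TPM over the cells of a pool was transformed as log2(TPM + 1), genes with a mean TPM of at least 1 in at least 2 pools were kept, and limma 3.58.1 in R 4.3.3 with eBayes and an intensity trend compared the 2 TMMp pools with the 2 ATML1p pools, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes, and the fit had 2 residual degrees of freedom. On simulated data from the same pools with 200 changed genes, this test recovered 67.5% of genes changed 4-fold, with 11 false calls, and 100% of those changed 16-fold or 64-fold, with 14 and 7 false calls. The changed genes were drawn from those of higher mean expression, and the noise was independent, at a spread smoothed over genes. Low genes and genes carried by few cells were therefore not covered. In the real pools SPCH, at 16.6-fold, missed the threshold. A total of 11 gene lists with 233 genes were tested with camera, with its preset correlation and again with an estimated one, and with fry. The lists were early stomatal lineage (24 genes), guard cell (15), epidermis and cuticle (21), trichome (10), mesophyll and photosynthesis (38), vasculature (18), S phase (18), G2 and M phase (23), endocycle and cell expansion (16), young leaf growth (19), and wounding and protoplasting stress (31).

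Reporter levels, shares of cells with a gene at a TPM of at least 1, and shares of cells per class were compared between 5 ATML1p and 7 TMMp plates with two-sided exact permutation tests over all 792 splits, whose smallest possible p was 0.00126. Intervals of shares are exact Clopper-Pearson 95% intervals. Spearman correlations were computed across the cells of each plate and their mean over plates was compared with 0 in a two-sided exact sign-flip test, which can give no p below 0.0156 with 7 plates or 0.0625 with 5. Genes following brightness were tested with limma on the Fisher z of the within-plate correlation for genes detected in at least 10% of TMMp cells. On simulated data with 200 changed genes, 77% of genes with a correlation of 0.2 and 100% of those with 0.4 were recovered, with 15 and 21 false calls. The changed genes were drawn only from widely detected genes. Recovery was therefore not measured for genes in few cells, such as SPCH (16.1% of TMMp cells) and FAMA (11.5%). Cells of both lines were clustered together on log2(TPM + 1) of 2000 variable genes without TMM and RCI2A, with 20 principal components, 15 nearest neighbours and the Leiden method at resolution 1 (scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2). A cluster was named "-like" only from the markers in the gene lists. Further computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and, in R, statmod 1.5.0 and data.table (1.17.8).

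Genes are named by a fixed rule. For the difference between lines, TMM, RCI2A, SPCH, MUTE, FAMA, EPF1, EPF2, BASL, POLAR and ATML1 were always reported, with the 8 largest rises and the 8 largest falls among genes past the threshold whose higher line had a mean of at least 10 TPM in both pools, and up to 4 members of each list with the largest change. For brightness, the rule took the 8 highest and 8 lowest correlations with 1 sign in every plate, and up to 3 members of each list. The alternatives tried changed the pseudocount, the filter on low genes, the summary over cells, the unit, the normalization, the cells kept, the trend in eBayes, the clustering and the detection limit, and left out each pool or plate in turn. Leaving out the mesophyll-like cells or the wider class that holds them at the lower cluster resolution, leaving out plate ML2, keeping cells with 2000 to 5000 genes and clustering without the list genes were chosen after seeing the data. Groups of 138 cytosolic ribosomal protein genes and 72 heat shock genes were taken from the annotation's product names after seeing the data. The correlations of their mean levels with genes detected, SPCH and FAMA were compared with those of 100 random gene sets matched on mean expression, and their differences between lines were not.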

Results

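The data covered 621 single cells of Arabidopsis seedling shoots, sorted into plates from 2 reporter lines and profiled with Smart-seq2. In the ATML1p line, an epidermal promoter drives YFP fused to RCI2A, a small membrane protein, and 143 cells came from 2 pools of 42 and 101 cells on 5 plates. In the TMMp line, YFP is fused to TMM, a receptor-like protein of the stomatal lineage, the cells that form the pores of the leaf epidermis, and 478 cells came from 2 pools of 142 and 336 cells on 7 plates. A cell had a median of 3179 genes at a TPM of at least 1 in ATML1p (range 377 to 9460) and 2777 in TMMp (range 384 to 10726). Plate ML2 of ATML1p, with 17 cells, had a median of 1311 genes, while the other ATML1p plates lay between 3055.5 and 3391. Transcripts encoded in the organelles took 8.83% and 7.68% of TPM in the ATML1p pools and 7.32% and 6.19% in the TMMp pools. Reads per cell could not be recovered from TPM, so the depth behind each value is unknown, and the intervals given for shares of cells cover the counting of cells only.

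The transcripts fused to YFP separated the lines. TMM averaged 1224 ± 227 TPM in TMMp and 30.1 ± 8.6 TPM in ATML1p (SD over 2 pools), and RCI2A averaged 789.8 ± 172 TPM in ATML1p and 266.7 ± 4.7 TPM in TMMp. TMM was detected in 90.2% of TMMp cells and 11.9% of ATML1p cells, and RCI2A in 46.9% and 74.1%. The YFP sequence was at 885 ± 219 TPM in TMMp and 967.9 ± 422 TPM in ATML1p, in 86% and 62.9% of cells. Across plates, TMM was 66.5-fold higher in TMMp and RCI2A 2.77-fold higher in ATML1p, each with an exact permutation p of 0.00126, the smallest possible (adjusted p = 0.00253 over 4 transcripts, 5 against 7 plates). RCI2B, a close relative of RCI2A that could share its reads, was at 29.1 and 29 TPM in the ATML1p pools and 1.5 and 1.9 TPM in the TMMp pools. Its log2 difference was -2.25 (exact permutation p = 0.048, adjusted p = 0.064). YFP differed by 0.02 on the log2 scale (adjusted p = 0.961 in the exact permutation test). The transgenes carry TMM and RCI2A sequence, so these levels are sums of the native gene and the reporter. With the mean of log2 values over cells in place of the mean TPM, all 4 transcripts passed the threshold.

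**Figure D1:**
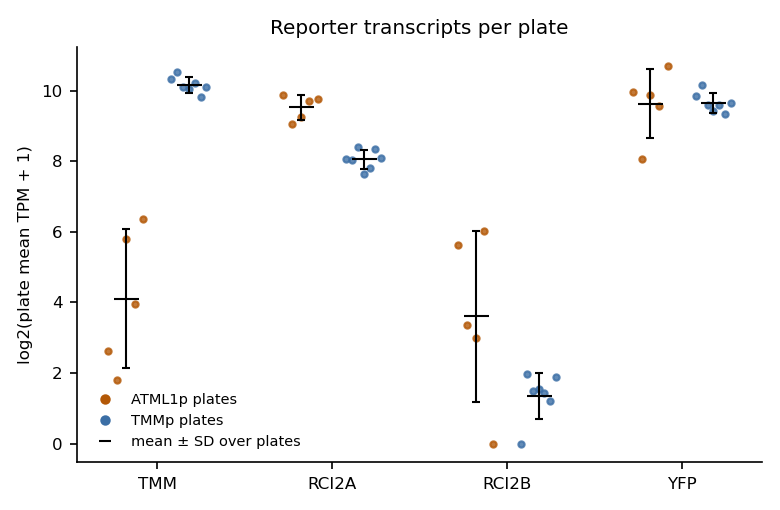
Mean TPM per plate of TMM, RCI2A, RCI2B and the YFP sequence as log2(TPM + 1), with 1 point per plate and bars for the mean and SD over 5 ATML1p and 7 TMMp plates. TMM plates lay between 2.5 and 82 TPM in ATML1p and between 894 and 1484 TPM in TMMp, with no overlap, while the YFP plates of both lines overlapped.

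The sorted cells also differed in the sorter's signals. YFP-channel signal was higher in ATML1p, at 12.72 ± 0.38 on the log2 scale against 10.97 ± 0.07 in TMMp (SD over 5 and 7 plates, exact permutation p = 0.00126, the smallest possible). Side scatter was also higher in ATML1p, at 11.23 ± 0.24 against 10.51 ± 0.16 (exact permutation p = 0.00126), and forward scatter, a proxy of cell size, was 16.64 ± 0.24 against 16.61 ± 0.06 (exact permutation p = 0.817). The settings of the sort gates were not given in the sources used here, and the gates could set the shares of cells reported for either line.

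The comparison of the lines asked which genes separate cells sorted by the TMM reporter from cells sorted by the epidermal one. DDF1, an AP2-type transcription factor, rose from 13.3 ± 3.06 TPM in ATML1p to 257.9 ± 54.2 in TMMp (SD over 2 pools, log2 difference 4.18 ± 0.36 SE). ATMYC1, a bHLH transcription factor, was at 0.38 ± 0.53 and 39.2 ± 4.21 TPM (4.92 ± 0.71), and HSP18.2, a small heat shock protein, at 6.36 ± 5.51 and 85.6 ± 23.8 TPM (3.77 ± 0.64), and both rose. TMM itself rose by 5.31 ± 0.33 on the log2 scale (adjusted p = 0.00576). AT1G34317, MLP423 and AT3G26960 rose by 4.86 ± 0.73, 4.52 ± 0.72 and 4.26 ± 0.76. AT3G48131 was at 15.6 ± 2.33 TPM in TMMp and listed at 0 in both ATML1p pools. Among genes with at least 10 TPM in both pools of the higher line, those that fell furthest averaged 0 to 2.42 TPM in TMMp, except AT3G05730, and some were detected in few ATML1p cells. AT3G16660 was at 1288 ± 1084 TPM in ATML1p and 0.03 ± 0.04 in TMMp (-9.98 ± 0.64), from 7.1% and 2% of the cells of the ATML1p pools. Its neighbour AT3G16670, with which it could share reads, was at 2301 ± 2852 TPM in ATML1p, from 4.8% and 4% of cells, and listed at 0 in TMMp, so the values of both are uncertain. AT1G22690, a gibberellin-regulated family member in the guard cell list (-9.43 ± 1.17), GASA1, another gibberellin-regulated gene (-8.11 ± 0.89), the glutathione transferase GSTU20 (-7.27 ± 0.62) and PBP1 (-7.06 ± 0.83) fell as well. AT3G05730 (-8.98 ± 1.39) was at 3308 ± 1888 TPM in ATML1p and 17.1 ± 24.1 TPM in TMMp, where its pools had 0.03 and 34.13 TPM. AT4G37409 was at 199.4 ± 20.5 TPM in ATML1p, from 2.4% and 3% of the cells of the pools, and listed at 0 in TMMp.

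Of the regulators fixed in advance, RCI2A fell by 1.55 ± 0.30 on the log2 scale (adjusted p = 0.0475), and this call ended without plate ML2 (adjusted p = 0.0501). SPCH, which starts the stomatal lineage, was at 31 ± 6.11 TPM in TMMp and 1.32 ± 1.86 in ATML1p (log2 difference 4.06 ± 0.83) and missed the threshold over all genes, with an adjusted p of 0.0549. BASL (3.49 ± 0.83), MUTE (2.93 ± 1.02), POLAR (2.68 ± 0.76), EPF2 (2.28 ± 0.66), FAMA (2.04 ± 0.85) and EPF1 (1.54 ± 0.56) were also above 0 without passing, with adjusted p values from 0.0776 for BASL to 0.221 for FAMA. ATML1 stood at -0.34 ± 0.41 (adjusted p = 0.671). In total, limma called 430 of 18390 genes, 85 higher and 345 lower in TMMp, with 2 pools per line. The median log2 difference of all tested genes was 0.32, and 0.16 after quantile normalization, so differences of gene groups are set against these values. Leaving out any 1 of the 4 pools gave 0 genes in limma, with 1435 to 6369 genes at an unadjusted p under 0.05. Plates as the unit gave 2786 genes, 1655 higher and 1131 lower, of which 392 were among the 430, and 2109 genes with a pool correlation added. With values capped at the 99th percentile of each gene, limma called 0 genes, with 3547 at an unadjusted p under 0.05. Without the mesophyll-like cells described with the cell classes, limma called 0 genes, with 3094 at an unadjusted p under 0.05. There the 345 genes had a median log2 difference of -2.68 (quartiles -4.4 to -0.82), from -3.27 (-4.4 to -2.46), as their median SE went from 0.45 to 0.58. The 85 genes had 2.05 (1.69 to 2.77), from 2.34 (1.97 to 3.13), and the lowest adjusted p of any gene was 0.0674. Without the 59 cells of the wider class into which these cells merge with cluster 9 at the lower cluster resolution, limma again called 0 genes, with 2665 at an unadjusted p under 0.05.

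Genes of photosynthesis fell together in TMMp. All 38 genes of the mesophyll and photosynthesis list were lower and past the threshold over all genes, and likewise all 38 when adjusted over the list alone. LHCB1.2, a light-harvesting protein of photosystem II, was at 22.7 ± 28.7 TPM in TMMp and 1301 ± 471 in ATML1p (log2 difference -6.68 ± 1.02 SE), and RBCS1B, a Rubisco small subunit, at 10.9 ± 15 and 330.8 ± 136 (-5.87 ± 1.15). LHCB2.3 (-4.78 ± 0.52) and LHCB1.4 (-4.59 ± 0.49) fell less far. The list median was -2.84 (camera adjusted p = 1.63e-48; adjusted p = 0.47 with an estimated correlation). The mesophyll-like cells, 37 in ATML1p and 3 in TMMp, moved with this list, and without them its median was -0.53, with 34 of 38 genes below 0, camera adjusted p = 1.39e-06 and adjusted p = 0.598 with an estimated correlation. Adjusted over the list alone, 2 genes were then lower and 1 higher. Without the wider class of 59 cells the median was -0.12, with 22 of 38 genes below 0 (camera adjusted p = 0.00513; 0.85 with an estimated correlation), and limma called 0 genes adjusted over the list alone (4 at an unadjusted p under 0.05). Without the mesophyll-like cells LHCB1.4 turned to 2.27 (adjusted p = 0.229).

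Genes of the early stomatal lineage were higher in TMMp as a group. Of 24 genes, 23 lay above 0, 4 rose past the threshold over all genes and 17 rose when adjusted over the list alone, with none lower. TMM, the sort reporter, is counted in these numbers and in the list tests. Its rise was set by the design, and the list was not tested without it. The count over the list alone was 1 without TMMp pool 1, 4 without TMMp pool 2, 10 without the mesophyll-like cells and 4 without the wider class. The risers over all genes were TMM, SOL1 (3.16 ± 0.39, adjusted p = 0.0139), HDG2, a homeodomain protein of the outer cell layer (2.78 ± 0.39, adjusted p = 0.0193), and the D-type cyclin CYCD7;1, at 11.2 ± 1.38 TPM in TMMp and listed at 0 in ATML1p. The protease gene SDD1 was at 79.8 ± 21.9 against 14.8 ± 20.9 TPM (adjusted p = 0.169). The list median was 2.32 (camera adjusted p = 2.14e-09; adjusted p = 0.47 with an estimated correlation), and 0.59 with means of log2 values over cells. With plates as the unit, the early stomatal, photosynthesis and S phase lists each had adjusted p = 0.0254 with an estimated correlation.

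Genes of DNA replication were also shifted upwards, with a median of 1.84 over 18 S phase genes (camera adjusted p = 1.31e-05; adjusted p = 0.531 with an estimated correlation). In limma 0 passed over all genes (11 at an unadjusted p under 0.05), and 7 rose when adjusted over the list alone: CYCA3;1, PCNA2, AT5G65360, CDC6, MCM5, MCM3 and PCNA1. MCM3, a subunit of the replicative helicase, was at 26.3 ± 11.8 TPM in TMMp and 2.54 ± 2.79 in ATML1p (3.15 ± 0.83), and CYCA3;1 and CDC6 were listed at 0 in ATML1p. Adjusted over the list alone, 14 S phase genes rose without ATML1p pool 1, 13 without plate ML2 and 4 without the mesophyll-like cells. None did in limma without TMMp pool 1, TMMp pool 2 or the wider class (4, 4 and 7 at an unadjusted p under 0.05). The S phase median was 0.82 without ATML1p pool 2 (camera adjusted p = 0.0204; 0.73 with an estimated correlation) and 0.52 with means of log2 values over cells. The 22 genes of G2 and M phase had a median of 0.81 (camera adjusted p = 0.0911; adjusted p = 0.856 with an estimated correlation), with 0 genes past limma's threshold over all genes (4 at an unadjusted p under 0.05) and 1 riser when adjusted over the list alone, CYCA2;3 (86.9 ± 37.5 against 17.1 ± 4.03 TPM). Without the mesophyll-like cells the G2 and M phase list passed, with a median of 1.52 and camera adjusted p = 0.0442 (adjusted p = 0.723 with an estimated correlation). It also passed without ATML1p pool 2 (median 1.135, camera adjusted p = 0.029; 0.73 with an estimated correlation) and without TMMp pool 2 (1.255, 0.0462; 0.724). Its median was 0.39 without ATML1p pool 1, 0.45 without TMMp pool 1, 0.5 without plate ML2, 1.425 without the wider class and 0.12 with means of log2 values over cells, and did not pass there. The 19 epidermis and cuticle genes had a median of 0.83 (camera adjusted p = 0.0124; adjusted p = 0.565 with an estimated correlation), 0 called over all genes by limma (7 at an unadjusted p under 0.05) and 4 risers when adjusted over the list alone, PDF1, LACS2, CER5 and GPAT4. PDF1, a marker of the outer cell layer, was at 935 ± 88.1 TPM in TMMp and 184.7 ± 145 in ATML1p. The epidermis list no longer passed without the mesophyll-like cells (median 0.66, camera adjusted p = 0.174), without the wider class (0.56, 0.988), without ATML1p pool 1 (0.65, 0.303) or without TMMp pool 2 (0.62, 0.085), and its median was 1.73 without ATML1p pool 2. Adjusted over the list alone, limma called 7 epidermis genes without ATML1p pool 2 and 0 without any 1 of the other pools, with 3 to 6 at an unadjusted p under 0.05.

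The other 6 lists did not pass camera. Of 12 guard cell genes (median 0.17, mean -0.69, camera adjusted p = 0.497, direction down), AT1G22690 fell over all genes. Adjusted over the list alone, STP1 and MYB60 rose and AT1G22690 and GORK fell. GORK, a potassium channel gene, was at 4.66 ± 1.26 TPM in ATML1p and listed at 0 in TMMp. Of 29 wounding and protoplasting genes, TCH2, a calmodulin-like protein, rose (1.56 ± 0.29, adjusted p = 0.0438) and LOX2, a lipoxygenase of jasmonate synthesis, fell (-4.89 ± 0.88, adjusted p = 0.0378). JAZ7, JAZ1 and CYP81F2 joined LOX2, and TCH2 stayed, when adjusted over the list alone (median 0.28, mean -0.24, camera adjusted p = 0.796, direction down). For these lists, and for the 3 trichome genes (median 0.24, mean -0.05, camera adjusted p = 0.814, direction down, 0 genes past limma's threshold over all genes or adjusted over the list alone, and 2 at an unadjusted p under 0.05), the median had the other sign than the mean and the test. Of 15 endocycle and cell expansion genes, the cell wall enzymes XTH24 (-4.13 ± 0.59) and XTH4 (-3.88 ± 0.71) fell, joined by EXPA11 when adjusted over the list alone (median -0.19, camera adjusted p = 0.238). Of 8 vasculature genes, the sulfate transporter gene SULTR2;1 was at 21 ± 0.97 TPM in ATML1p and listed at 0 in TMMp (adjusted p = 0.0247). ACL5 (-5.33 ± 1.09) fell too when adjusted over the list alone (median -0.13, camera adjusted p = 0.122). Without the mesophyll-like cells the vasculature list passed (camera adjusted p = 0.0442; adjusted p = 0.508 with an estimated correlation), and without the wider class it did not (median 0.38, camera adjusted p = 0.988). Without that class the guard cell list passed (median -0.32, camera adjusted p = 0.012; 0.823 with an estimated correlation). With either TMMp pool left out, limma called 0 guard cell, wounding and vasculature genes adjusted over the list alone, with 2 to 6 per list at an unadjusted p under 0.05, and 1 endocycle gene. The 16 young leaf growth genes had 0 genes past limma's threshold over all genes or adjusted over the list alone and 5 at an unadjusted p under 0.05, with YAB3 at 2.71 ± 0.97 and GIF1 at -2.55 ± 0.97 (median -0.12, camera adjusted p = 0.739). With all cells and an estimated correlation, the adjusted p of these 6 lists ranged from 0.544 for vasculature to 0.915 for trichome and wounding.

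**Figure D2:**
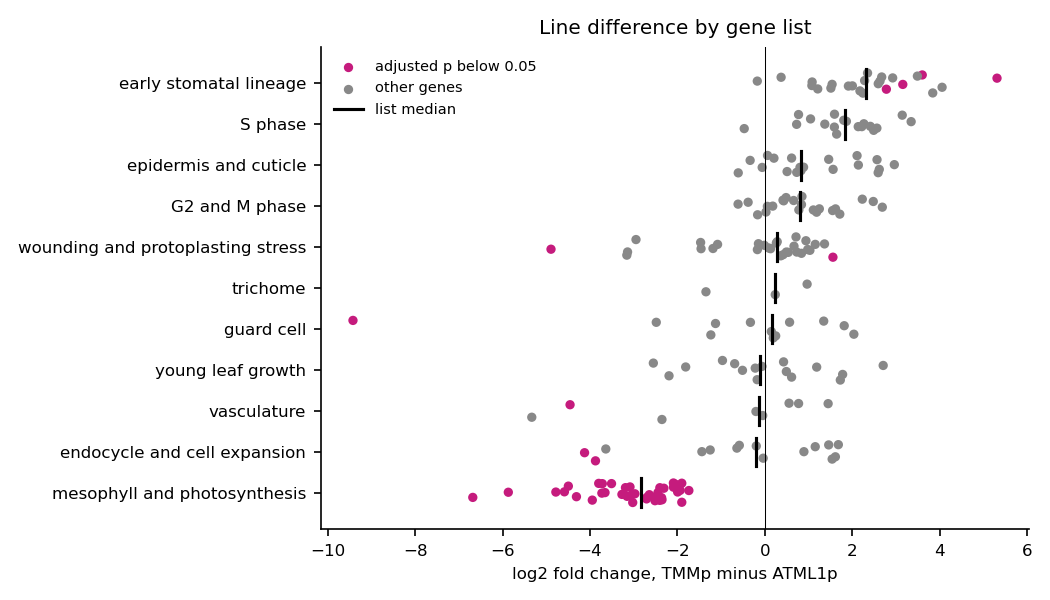
Log2 difference in TPM + 1, TMMp minus ATML1p, of each gene in the 11 lists, with 1 point per gene, coloured points for genes past the adjusted p of 0.05 over all genes and a bar at the list median. All 38 photosynthesis genes lay below 0 and 23 of 24 early stomatal genes, with the sort reporter TMM among them, above 0.

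The share of cells with a stage gene at a TPM of at least 1 was compared by plate, in a fixed set of 15 genes. POLAR, a polarity protein of dividing lineage cells, was detected in 27.8% ± 6.8 of TMMp cells and 6.8% ± 3 of ATML1p cells (SD over 7 and 5 plates), and SPCH in 15.9% ± 5.8 and 2.5% ± 4. PDF1 was in 58% ± 5.5 of TMMp cells against 10.1% ± 6.3. In the other direction, SCAP1, a transcription factor of maturing guard cells, was in 1.7% ± 1.3 of TMMp and 8% ± 3.2 of ATML1p cells, and ATML1, the epidermal regulator whose promoter drives the other reporter, in 35.5% ± 10.3 and 59.1% ± 10. FAMA, which acts at the last division of the lineage, was in 11.4% ± 4.1 and 11% ± 4.8 of cells.

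In exact permutation tests of 5 against 7 plates, 11 of the 15 genes passed after adjustment. Adjusted p was 0.00947 for POLAR, SPCH, PDF1 and SCAP1, and 0.0135 for ATML1, EPF2 and BASL. MUTE, which ends the amplifying divisions, was in 7.3% ± 2.9 of TMMp and 2.5% ± 2.6 of ATML1p cells (adjusted p = 0.0241 in the exact permutation test). EPF1 (10.4% against 4.2%), MYB60 (17.5% against 5.9%) and CDKB1;1 (8.5% against 2.9%) also passed. FAMA (adjusted p = 0.912, exact permutation), CYCB1;1 (7.1% against 5.8%), the phloem gene SUC2 (4.8% against 2.6%) and RBCS1A (75.9% against 81.6%, adjusted p = 0.294, exact permutation) did not. RBCS1A was thus found in most cells of both lines, while its level was 7046 and 7729 TPM in the ATML1p pools and 836 and 1055 TPM in the TMMp pools. SPCH was detected in 0 of 42 cells of ATML1p pool 1, which allows a share of up to 8.41% (exact Clopper-Pearson 95% interval), 4 of 101 in pool 2, and 30 of 142 and 47 of 336 in the TMMp pools. In cells with at least 1000 genes, MUTE no longer passed (adjusted p = 0.0517, exact permutation).

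**Figure D3:**
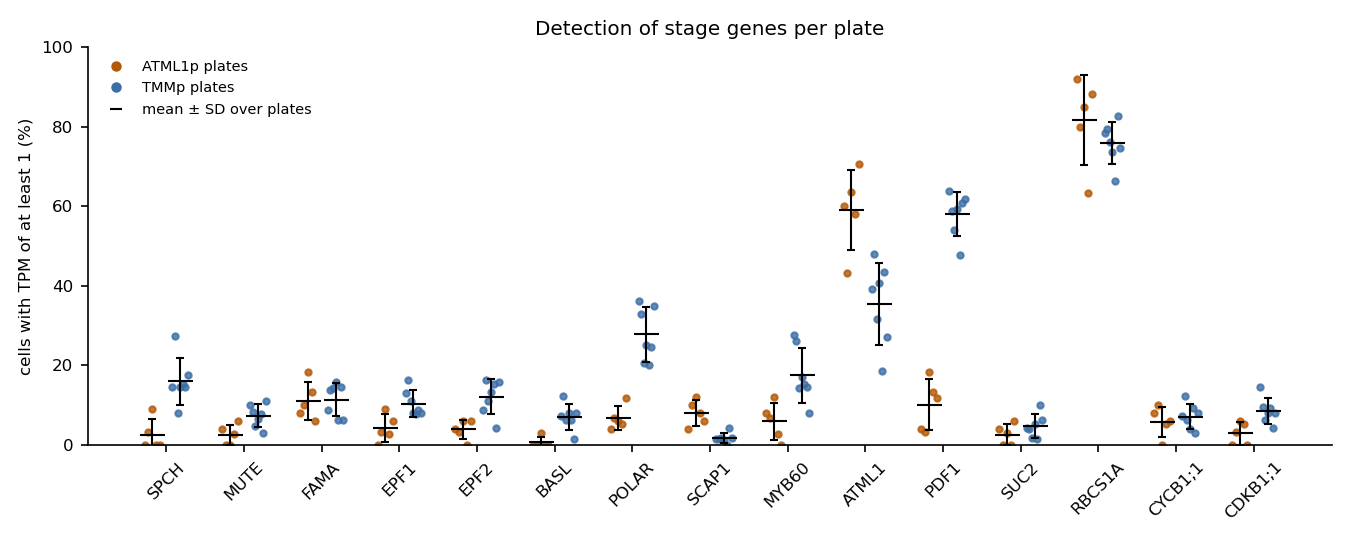
Percent of cells with a TPM of at least 1 for 15 genes, with 1 point per plate and bars for the mean and SD over 5 ATML1p and 7 TMMp plates. POLAR lay above all ATML1p plates in 7 of 7 TMMp plates, and the FAMA plates of both lines overlapped.

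Within TMMp plates, genes of the same stage were correlated across cells. SPCH and BASL, which marks asymmetric division, had a mean Spearman rho of 0.524 ± 0.236 (SD over 7 plates), MUTE and EPF1, a secreted peptide of the later stages, 0.356 ± 0.19, SPCH and EPF2, the peptide of the early stage, 0.252 ± 0.175, and BASL and POLAR 0.215 ± 0.123. TMM followed SPCH (0.312 ± 0.102), ATML1 (0.299 ± 0.081) and RBCS1A (0.39 ± 0.144). Each of these 7 pairs was positive in 7 of 7 plates, with an exact sign-flip permutation p of 0.0156, the smallest possible (adjusted p = 0.0357 over 16 pairs). SPCH with POLAR (0.232) and CDKB1;1, a kinase of the stomatal divisions, with SPCH (0.221), MUTE (0.13) and FAMA (0.225) were positive in 6 of 7 plates (adjusted p = 0.0455, exact permutation).

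For the regulators of successive stages, cells with both genes were also counted. Of 478 TMMp cells, 77 had SPCH, 35 had MUTE and 55 had FAMA, and 14 had SPCH with MUTE, 8 SPCH with FAMA and 1 MUTE with FAMA. Their correlations did not pass: 0.159 ± 0.168 for SPCH and MUTE (adjusted p = 0.0962, exact permutation over 7 plates), -0.064 ± 0.093 for MUTE and FAMA (adjusted p = 0.143) and -0.013 ± 0.137 for SPCH and FAMA (adjusted p = 0.781). Neither did EPF1 and EPF2 (-0.014 ± 0.136) nor FAMA and SCAP1 (0.261 ± 0.157 over 6 plates, adjusted p = 0.0833, exact permutation). Given the number of genes detected, 6 pairs passed (adjusted p = 0.0417, exact permutation): SPCH with BASL (0.506), EPF2 (0.208) and TMM (0.178), MUTE with EPF1 (0.306), TMM with RBCS1A (0.193) and BASL with POLAR (0.163). The calls of TMM with ATML1 (0.076, adjusted p = 0.183, exact permutation), SPCH with POLAR (0.138) and CDKB1;1 with SPCH (0.131), MUTE (0.055) and FAMA (0.122) were lost. With any 1 plate left out none of the 16 pairs passed, in a test that allows no exact permutation p below 0.0312 with 6 plates. TMM and RBCS1A had a mean rho of -0.164 in ATML1p, below the 0.39 in TMMp (exact permutation p = 0.00126 for the difference of 0.554, adjusted p = 0.00253). The measures were unlike: TMM included the transgene in TMMp and was the native gene alone in ATML1p, where 11.9% of cells had it and 13 had both genes. The mesophyll-like cells were kept, and the difference was not computed given genes detected. With the same limits, TMM and ATML1 had 0.159 in ATML1p, where 14 cells had both, against 0.299 in TMMp (difference 0.14, adjusted p = 0.0417, exact permutation).

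The cells of both lines were grouped into 11 clusters, of which 5 were named from the fixed markers. Mesophyll-like cells, higher for all 38 photosynthesis genes, made up 24.8% ± 15.9 of ATML1p plates (37 cells) and 0.7% ± 0.8 of TMMp plates (3 cells). Guard cell-like cells led by TGG1, a myrosinase, made up 8.1% ± 5.2 of ATML1p plates (12 cells), and none of the 142 and 336 cells of the TMMp pools, which allows up to 2.56% and 1.09%. HSP17.4, GSTU24 and CYP81D11, genes of heat and chemical stress, were among the leading genes of that class. S phase-like cells, led by histone genes, were 8.8% ± 1.2 of TMMp plates (42 cells) and 2.4% ± 5.3 of ATML1p plates (2 cells, both on plate ML2). Guard cell-like cells with high FAMA were 8.9% ± 4.2 of TMMp and 4.2% ± 4.6 of ATML1p plates, and G2 and M phase-like cells 3.7% ± 2.1 and 2.5% ± 4. The names leave out other markers. S phase-like cells were higher for 12 of 18 S phase and 18 of 24 early stomatal genes. G2 and M phase-like cells were higher for 23 of 23 and 18 of 24, and both classes had many genes per cell (medians 4618 and 5690). FAMA-high cells were higher for 6 of 15 guard cell and 11 of 21 epidermis genes.

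The exact permutation test of 5 against 7 plates, adjusted over the 5 classes, passed for mesophyll-like (adjusted p = 0.00631), TGG1-high guard cell-like and S phase-like cells (both 0.0189), and not for FAMA-high guard cell-like (0.126) or G2 and M phase-like cells (0.508). Clustered without the list genes, a setting chosen after seeing the data, mesophyll-like cells differed by -23.5 percentage points (adjusted p = 0.00631, exact permutation) and TGG1-high guard cell-like cells by -8.1 (0.0253), while S phase-like cells differed by 3.3 and no longer passed (0.172). The S phase-like call was also lost at resolution 0.5 (3.1 points, adjusted p = 0.279) and 2 (3.3, 0.145), with 1000 variable genes (4.2, 0.0852), with genes centred within plates (4, 0.0931) and in cells with 2000 to 5000 genes (1.1, 1), all by exact permutation. The difference was 22.1 points with 4000 variable genes, where the class held 119 cells in place of 44 and was no longer the same class. In the clusterings that lost the call it held 28 to 33 cells. FAMA-high guard cell-like cells passed with genes centred within plates (5.9 points, adjusted p = 0.0463, exact permutation). At the lower cluster resolution the guard cell classes merged, and mesophyll-like cells alone passed (-38.8 percentage points, adjusted p = 0.00505, exact permutation). Among unnamed clusters, cluster 9, led by the aquaporin PIP2A and higher for 27 of 38 photosynthesis genes, held 14.7% ± 7.1 of ATML1p plates (19 cells) and no TMMp cell. Cluster 3, with PDF1 among its leading genes, held 13.1% ± 4.1 of TMMp plates and 0 of 143 ATML1p cells. Cluster 0, led by heat shock genes including HSP70 and HSP101, held 27.4% ± 8.6 of TMMp and 4.2% ± 2.7 of ATML1p plates. Cluster 4, with a median of 1186 genes per cell, held 5.6% ± 1.1 and 25.3% ± 11.4. Cluster 1 (20.7% ± 5.2 against 5.6% ± 3.3) differed as well, each of these 5 with adjusted p = 0.00231 over 11 clusters (exact permutation), and cluster 2 did not (11.2% ± 2.2 against 8.3% ± 6.9, adjusted p = 0.369). Sort gates and genes per cell could set these shares.

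**Figure D4:**
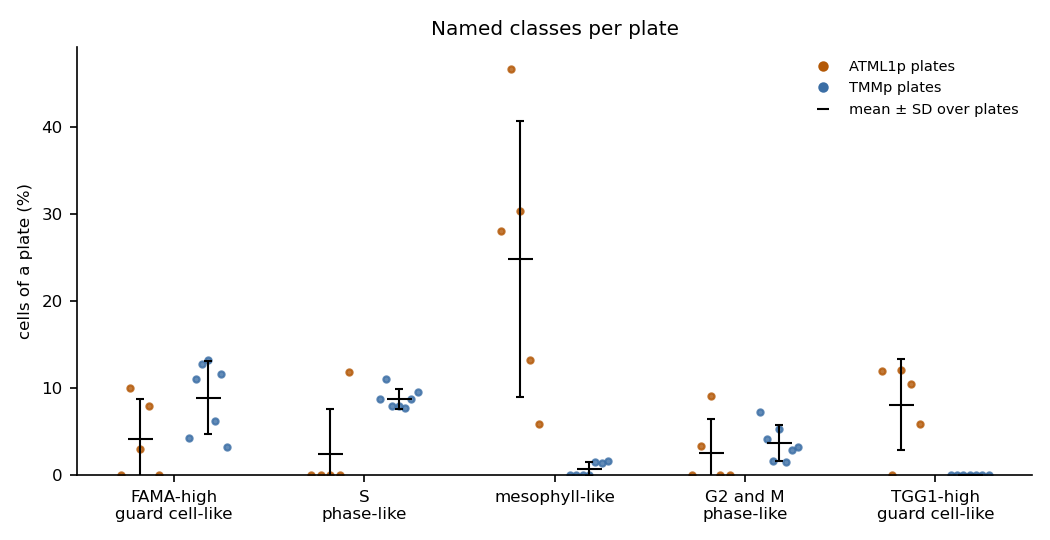
Percent of the cells of a plate in each of the 5 named classes, with 1 point per plate and bars for the mean and SD over 5 ATML1p and 7 TMMp plates. Mesophyll-like cells averaged 24.8% of ATML1p and 0.7% of TMMp plates, and no TMMp plate held TGG1-high guard cell-like cells.

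Whether a cell's YFP signal in the sorter followed its reporter transcript was asked within plates. In TMMp, YFP signal and TMM had a mean Spearman rho of 0.006 ± 0.116 (SD over 7 plates, positive in 4), and YFP signal and the YFP sequence 0.032 ± 0.122 (positive in 5). In ATML1p, YFP signal and the YFP sequence had 0.353 ± 0.136 (SD over 5 plates, positive in all 5), and YFP signal and RCI2A 0.138 ± 0.156. None passed the exact sign-flip permutation test after adjustment (adjusted p = 0.891 for TMM and 0.688 for YFP in TMMp, 0.25 for YFP and 0.375 for RCI2A in ATML1p), and 5 plates allow no p below 0.0625. The difference between the lines in the correlation with the YFP sequence was -0.321, with an exact permutation p of 0.00126, the smallest possible (adjusted p = 0.00253), and that between TMM in TMMp and RCI2A in ATML1p was -0.131 (exact permutation p = 0.124). Given the number of genes detected, the correlation with TMM was -0.23 and that with YFP in TMMp -0.199.

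Across TMMp cells, brightness in the YFP channel was related to many other genes. Its correlations with the TMM transcript and the YFP sequence had not passed, so how much of it came from TMM-YFP is unknown. Of the genes with the same sign in all 7 plates, AT4G27090 had the highest mean within-plate rho, 0.297 ± 0.1 (SD over plates). Ribosomal protein genes followed, among them AT2G40205 of the L41 family (0.293 ± 0.138), AT3G60245 (0.288 ± 0.124), AT1G27400 (0.281 ± 0.156), AT3G16780 (0.28) and AT4G13170 (0.28), as well as AT3G51270 (0.287) and AT5G20160 (0.285). SPCH (0.241 ± 0.122, limma adjusted p = 0.000544), PDF1 (0.238 ± 0.122, adjusted p = 0.000575) and POLAR (0.162 ± 0.163, adjusted p = 0.0122) rose with brightness, and FAMA fell, at -0.159 ± 0.121 and negative in 7 of 7 plates (adjusted p = 0.0104). On the falling side stood AT1G76600 (-0.236 ± 0.107), the glutathione transferase GSTF8 (-0.231 ± 0.179), the transporter PEN3 (-0.184 ± 0.055), the ubiquitin gene UBQ10 (-0.181), the alternative oxidase AOX1A (-0.169), AT1G75860 (-0.201), AT2G39690 (-0.191) and AT1G23710 (-0.186).

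The limma test called 2337 of 9412 genes, 2274 rising and 63 falling, and the median rho of all genes was 0.0762. Left out in turn, plate TMM-1 raised the count to 3601, and plates TMM-2, TMM3, TMM4 and TMM6 lowered it to 1356, 1297, 1432 and 1245. Falling genes were 30 without plate TMM3, 38 without TMM5 and 40 without TMM6. Brightness was itself correlated with forward scatter, by 0.248 to 0.658 over the plates, and with the number of genes detected, by -0.037 to 0.502. Given both, 300 genes passed, 204 rising and 96 falling, of which 235 were among the 2337. SPCH (0.154, adjusted p = 0.0266), PDF1 (0.144, adjusted p = 0.0427) and FAMA (-0.239, adjusted p = 0.000978) kept their calls, and POLAR did not (0.084, adjusted p = 0.317). FAMA lost its call on the plates of pool 2 (-0.121, adjusted p = 0.061) and without plate TMM3 (-0.131, adjusted p = 0.0715). Tested in the same way, forward scatter gave 3292 genes, 3285 rising and 7 falling, and 2111, 1806 and 1868 genes without plates TMM-2, TMM4 and TMM6.

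By list, the 13 S phase genes had a median rho of 0.143, with 8 risers over all genes, such as the histone gene AT1G09200 (0.261 ± 0.1) and PCNA2 (0.2 ± 0.105), and 11 when adjusted over the list alone (camera adjusted p = 0.00549; 0.487 with an estimated correlation). Set against the other genes, the 22 wounding and protoplasting genes stood lower, with a median of -0.00247 and a mean of 0.00272, the transcription factors WRKY53 and ERF6 rising, WRKY33 falling and none called when adjusted over the list alone (camera adjusted p = 0.000113; 0.349 with an estimated correlation). The 7 guard cell genes stood lower too, with a median of -0.00695 and FAMA as the single call, also when adjusted over the list alone (camera adjusted p = 0.00549; 0.349 with an estimated correlation). Both medians lay near 0 and turned above it without plate TMM-1 (0.018 for wounding and 0.026 for guard cell) or TMM3 (0.00674 and 0.0104), and that of wounding also without TMM4 (0.0225) or TMM5 (0.000652). The remaining lists did not pass camera with all 7 plates. The photosynthesis list passed on the plates of pool 2 (median 0.131, camera adjusted p = 0.00833; 0.281 with an estimated correlation) and without plate TMM-1 (0.14, 0.0136; 0.356). Risers over all genes, and when adjusted over the list alone, were 8 and 11 of 16 early stomatal genes (median 0.122, camera adjusted p = 0.213), 13 and 17 of 34 photosynthesis genes (median 0.107, adjusted p = 0.195) and 3 and 5 of 14 epidermis genes (median 0.0612, adjusted p = 0.75). They were 2 and 2 of 4 young leaf growth genes (median 0.123, adjusted p = 0.251), with CYCD3;2 at 0.208 ± 0.104, and 1 and 1 of 2 endocycle genes (median 0.132, adjusted p = 0.408), with EXP3 at 0.217 ± 0.098. The single genes tested for G2 and M phase, CYCA2;3 (0.07, adjusted p = 0.267), and for trichomes, TTG1 (0.046, adjusted p = 0.468), were not called, and no vasculature gene was detected in enough cells. Given forward scatter and genes detected, limma's risers over all genes fell to 0 for S phase (5 genes at unadjusted p under 0.05, 1 when adjusted over the list alone, median 0.0776, camera adjusted p = 0.0148; 0.305 with an estimated correlation). They fell to 1 for early stomatal and 0 for photosynthesis genes (5 and 6 genes at unadjusted p under 0.05 by limma), and the wounding list no longer passed (camera adjusted p = 0.516). The guard cell genes stood further below, at a median of -0.0796 with 7 of 7 below 0, 1 called over all genes and 2 when adjusted over the list alone (camera adjusted p = 6.44e-05; 0.256 with an estimated correlation). The wounding list also stood lower for forward scatter itself (camera adjusted p = 1.25e-05; 0.0345 with an estimated correlation). With an estimated correlation that call was lost on the plates of pool 2 (0.216) and without plate TMM-1 (0.064), TMM-2 (0.1), TMM3 (0.0568), TMM4 (0.176) or TMM5 (0.071).

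**Figure D5:**
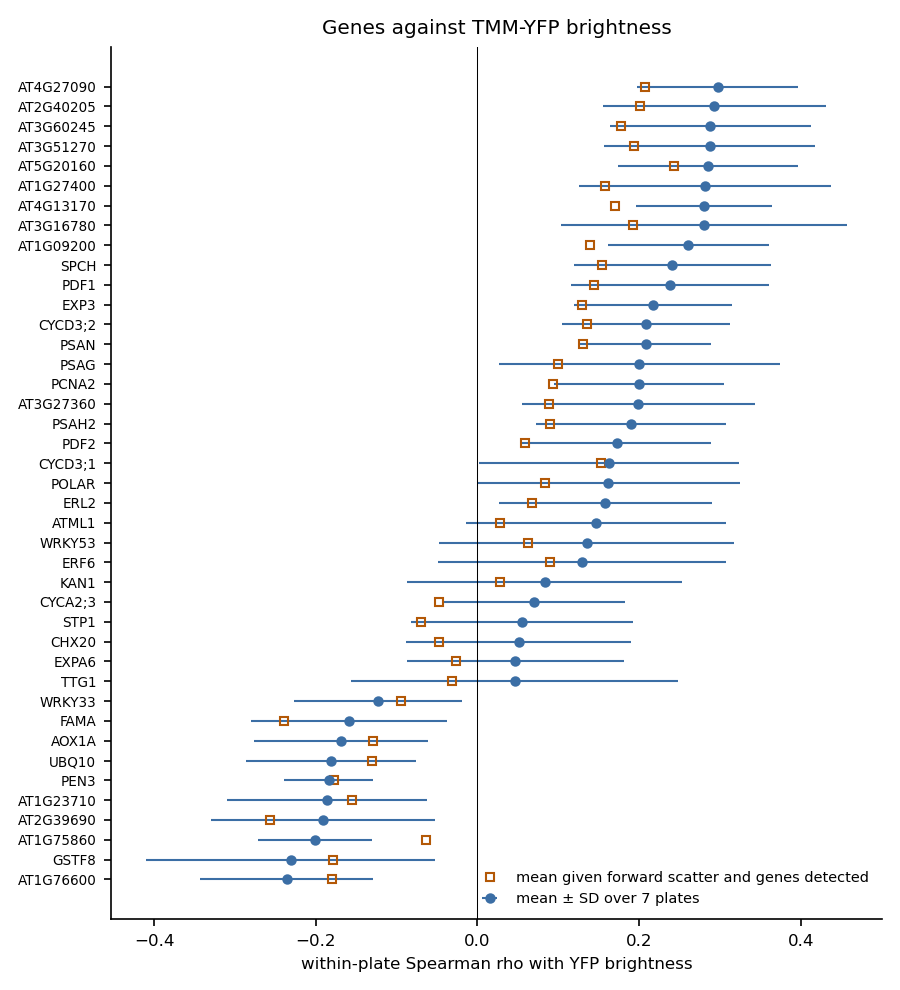
Mean within-plate Spearman rho of named genes with YFP signal in TMMp cells, with filled points and bars for the mean and SD over 7 plates and open squares for the mean given forward scatter and genes detected. Of the plotted genes, AT4G27090 stood highest at 0.297 and AT1G76600 lowest at -0.236, and FAMA moved from -0.159 to -0.239 given both measures.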

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

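The tests of size and depth for ribosomal genes and FAMA, of the order of brightness and of the splits of plates and pools, and the alternatives without the mesophyll-like cells, without the wider class and in cells with 2000 to 5000 genes, were chosen after the results were seen.

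Some plates stood apart from the others of their line in a test of the gap to the nearest plate, run on 90 groups of plates, and 10 were found. The limit is set for about 1 such group in 20 by chance in normally spread values. Many groups were percentages with plates at 0, where few cells decide, so the count of 10 cannot be set against chance. RCI2B was at 0 log2(TPM + 1) on plate TMM-1, against 1.23 to 1.96 on the other TMMp plates. BASL was detected in 3.03% of cells on plate ML1-6 and in 0% on the other ATML1p plates, and SCAP1 in 4.35% on plate TMM6, against 0 to 1.59% on the other TMMp plates. The rho of MUTE and FAMA was 0.145 on plate TMM6, where the other plates lay between -0.119 and -0.0738, and that of SPCH and EPF2 was 0.637 on plate TMM3, where the others lay between 0.134 and 0.271. Plate TMM-1 had a rho of -0.217 between brightness and the YFP transcript, against -0.0139 to 0.139 elsewhere in TMMp, and held 21.7% of its cells in cluster 3, against 9.23% to 14.5%. Plate ML2 had a median of 1311 genes per cell and held 11.8% S phase-like cells, a class absent from the other ATML1p plates, and plate ML1-5 held 0% in cluster 1, against 5.88% to 8%. The lines differed in the rho of TMM with ATML1, by 0.14, and of TMM with RBCS1A, by 0.554, each in the exact permutation test, and with the limits, given with the pairs.

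The 345 genes lower in TMMp had a median log2 difference of -3.27, and the photosynthesis list -2.84, beside the mesophyll-like cells in the ATML1p sort. Without the 40 cells of that class, the 302 called genes of no list had a median of -2.97 (quartiles -4.59 to -1.16), from -3.32 (-4.48 to -2.47). Their calls ended, as their median SE went from 0.46 to 0.59 and limma called 0 genes, with 218 of the 302 at an unadjusted p under 0.05. The 302 genes were picked as lower in the same pools, so part of what remained could come from that choice. The 40 cells thus did not carry the whole measured difference, and the cause of the rest was not decided. The 19 ATML1p cells of cluster 9, which merge with this class at the lower cluster resolution, stayed in. So did the 12 TGG1-high guard cell-like cells, all in ATML1p. Without all 59 cells the median was -2.12 (quartiles -3.7 to -0.23), the median SE 0.64 and 148 of the 302 had an unadjusted p under 0.05. For the 302 genes this wider class and a difference between the remaining cells cannot be told apart, since the upper quartile came near 0. In cells with 2000 to 5000 genes, the 345 genes had a median of -2.91 (quartiles -4.04 to -2.18). There 1 call was left, the median SE was 0.55, from 0.45, and 297 had an unadjusted p under 0.05. With the same limit of genes picked in these pools, cells outside that range did not carry the whole measured difference. The part of genes detected per cell stays open. For the photosynthesis list, at -0.53 without the mesophyll-like cells and -0.12 without the wider class, their presence and a lower level in the remaining cells cannot be told apart, since the cells were grouped partly by these genes. Doublets with an epidermal cell were argued against as the source of the whole class by 1.16 ± 1.21 epidermis genes per mesophyll-like ATML1p cell, against 3.7 ± 3.46 in other ATML1p cells. A class mean cannot exclude them for single cells. The YFP sequence was in 24.3% of the mesophyll-like cells (9 of 37, exact 95% interval 11.77 to 41.2) and 76.4% of the other ATML1p cells. It was lower on all 5 plates (exact permutation p = 0.0625, the smallest possible), on plate ML2 from 1 mesophyll-like cell. A candidate explanation is therefore that cells without the reporter passed the gate by their own fluorescence, and weak promoter activity in mesophyll stays open, as untested.

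Brightness followed the YFP transcript more closely in ATML1p than in TMMp, by -0.321 in mean rho, TMMp minus ATML1p. The number of genes detected was argued against, since the difference given that number was -0.59 (exact permutation p = 0.00126, the smallest possible). A narrower range of brightness in TMMp, with a within-plate SD of 0.61 against 1.33 on the log2 scale, cannot be told apart from a difference between the lines: in 77 ATML1p cells trimmed to the TMMp spread the mean rho was 0.149 ± 0.184 over 5 plates, and the difference was -0.117 (exact permutation p = 0.213). The mesophyll-like cells of ATML1p, with the YFP sequence in 24.3% against 76.4% of the other cells, were kept in these correlations. Their mean signal was 12.25 ± 1.13 against 12.92 ± 1.37 (SD over cells), and the mean difference over plates was -0.18 (exact sign-flip permutation p = 0.75). Plate ML2, with 1 mesophyll-like cell, had a difference of 1.34, while the other plates lay between -0.99 and -0.19. The mean over plates thus leaned on 1 cell and does not settle whether the signal differed. No correlation was computed without them, so their part was not tested. A difference between the reporter fusions, which the lines confound with the sort, stays open, as untested.

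The 2337 genes related to brightness in the YFP channel of TMMp cells were not a matter of chance order: of 100 orders of brightness within plates, 1, the real one, gave as many, and the highest of the others gave 13. Ribosomal protein genes, grouped after several of them led these correlations, had a median rho of 0.21 and, given forward scatter and genes detected, 0.126. There the quartiles were 0.092 to 0.153, 120 of 120 genes lay above 0, and 44 were called against 115 before. Both measures were taken out of brightness only and stand in imperfectly for size and depth. They did not account for the whole correlation, while size and depth themselves stay open for these genes. For FAMA, at -0.239 given both, cell size and genes detected were argued against as the whole cause. For the genes that were not called given both measures, 300 against 2337 in all, size and depth stay open as well. That brightness follows the stage of a cell in the lineage may be a hypothesis for SPCH and FAMA, and no biological explanation was tested, since the labels give no stage. How much of the brightness came from TMM-YFP is also unknown.

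The difference between lines with plates as the unit called 2786 genes. Of 100 splits of the 12 plates into 5 and 7, 1, the real one, gave as many, and the highest of the others gave 4, so chance can be excluded for this count only where plates are independent. The plates came in 4 pools, which the real split keeps whole and most others mix, and with a pool correlation the count was 2109. Of 3 splits into 5 and 7 plates that keep pools whole, the highest of the others gave 98, and 3 splits are too few for a share under 0.05. Differences between pools or plates that follow the lines stay open.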

How the results depend on the processing

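Leaving out the mesophyll-like cells or the wider class of 59 cells that holds them at resolution 0.5, leaving out plate ML2, keeping cells with 2000 to 5000 genes and clustering without the list genes were chosen after seeing the data. Over 183 results and 1766 recomputed values, 1232 were labelled the same, 298 fell short of the threshold, 86 newly passed it, 67 changed sign, and 83 values without a test of their own moved. For tested values the same meant direction and side of the threshold kept, also where neither setting passed. For counts it meant a change within a fixed fold limit, and for correlations within pools a shift under the SD over plates. The 1232 are thus not a count of findings that held. The cause was not tested unless stated. With 2 pools per line and no read counts, sampling noise per gene could not be set apart from spread between pools.

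For the line difference (430 genes, 85 higher, 345 lower), limma called 153 (14 higher, 139 lower) with a pseudocount of 0.1, 668 (158 higher) with a filter of 5 TPM, 1001 (369 and 632) with means of log values and 842 (199 and 643) after quantile normalization. It called 2786 (1655 and 1131) with plates as the unit and 2109 (1230 and 879) with a pool correlation added. It called 0 genes, 0 higher and 0 lower, without a filter, with capped values, without the trend, without the mesophyll-like cells, without the wider class and with any 1 pool left out (range 0 to 0), where 4015, 3547, 3635, 3094, 2665 and 1435 to 6369 genes had an unadjusted p under 0.05. Cells with 2000 to 5000 genes gave 1 gene, 0 higher and 1 lower, with 2873 at an unadjusted p under 0.05. With a pool left out, its line had 1 pool, assumed to vary like the other line. Pool number as a replicate block gave 1696 genes (692 higher, 1004 lower), 430 of them shared; deviations of same-numbered pools had a correlation of 0.047, so the numbers were not taken as pairs.

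List medians changed sign for young leaf growth (0.26 with a pseudocount of 0.1 and 0.26 without the mesophyll-like cells), endocycle (0.025 with means of log values), guard cell (-0.08 with means of log values, -0.12 without the mesophyll-like cells) and trichome (-0.054 with means of log values). Without the wider class they were 0.644 for endocycle, -0.321 for guard cell, 0.382 for vasculature and 0.743 for young leaf growth. With a pool left out they ranged from -0.63 to 0.45 for guard cell, -0.88 to 1.35 for trichome, -0.14 to 0.66 for wounding, -0.26 to 0.36 for young leaf, -0.57 to 0.27 for endocycle and -0.73 to 0.19 for vasculature. Among genes, LHCB1.4 was 2.27 without the mesophyll-like cells, CPC -0.054 with means of log values, -0.083 after quantile normalization and -0.88 to 1.35 with a pool left out, and ATML1 -0.676 to 0.003 with a pool left out.

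Of the reporter transcripts, 4 passed with means of log values, RCI2B at -0.30 and YFP at 1.93. FAMA detection differed by -0.32 points at a TPM of at least 10, -0.05 in cells with at least 1000 genes and -0.98 without plate ML2. In cells with either gene above 0, which builds exclusion into the measure, rho was -0.553 for SPCH and MUTE, -0.436 for SPCH and EPF2, -0.323 for SPCH and POLAR, -0.210 for MUTE and EPF1, -0.074 for FAMA and SCAP1 and -0.107 for BASL and POLAR. For CDKB1;1 it was -0.495 with SPCH, -0.633 with MUTE and -0.293 with FAMA. Given genes detected, 6 pairs passed. With 1 plate left out 0 passed (0 to 0), and rho ranged from -0.052 to 0.014 for SPCH and FAMA and -0.047 to 0.005 for EPF1 and EPF2. The Spearman correlation of TMM and YFP signal was -0.009 with the signal divided by forward scatter, -0.230 given genes detected and -0.014 to 0.039 with 1 plate left out, and that of the YFP sequence and signal in TMMp was -0.199 given genes detected. At resolution 0.5, 1 class passed.

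For brightness (2337 genes, 2274 rising, 63 falling), fewer genes tested, those in at least 25% of cells, gave 1037 (981 rising), forward scatter 1711, and 1 list in place of 3, with 1 S phase and 2 guard cell genes left, too few for a list test. Given scatter and genes detected, 300 passed (204 and 96). With 1 plate left out, counts were 1245 to 3601 (1205 to 3511 rising, 30 to 90 falling), and 1806 to 3429 for forward scatter. The median rho of guard cell genes was 0.0242 in genes in at least 25% of cells, 0.022 on pool 2 plates, -0.0796 given both and -0.0181 to 0.026 with 1 plate left out, and that of wounding genes 0.00234 on pool 2 plates, 0.000993 given both and -0.0189 to 0.0225 with 1 plate left out. Given both, medians were -0.0245 for epidermis, -0.0471 for G2 and M phase and -0.0322 for trichome, and rho was -0.026 for EXPA6, -0.047 for CYCA2;3, -0.07 for STP1, -0.048 for CHX20 and -0.032 for TTG1.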

Other observations

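The ribosomal and heat shock gene groups were taken from the annotation after the gene results had been seen, and comparing them with matched gene sets was added after their own results had been seen.

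Genes of cytosolic ribosomal proteins moved with SPCH in TMMp cells. Their mean level had a mean within-plate rho of 0.43 with SPCH, positive in 7 of 7 plates (exact permutation p = 0.0156, the smallest possible), above the -0.05 to 0.282 of 100 random gene sets matched on mean expression. Of 120 such genes detected widely enough, 115 rose with brightness in the YFP channel and 0 fell, and 44 were called given forward scatter and genes detected. Over plates the level was 3.31 ± 0.3 in TMMp and 2.8 ± 0.48 in ATML1p on the log2(TPM + 1) scale (SD over 7 and 5 plates, difference 0.51, exact permutation p = 0.0278), while limma called 0 of 128 single genes between the lines, with 47 at an unadjusted p under 0.05. A hypothesis was that the same genes fall as FAMA rises, and the data did not decide it. The mean rho with FAMA was 0.037, negative in 2 of 7 plates (exact permutation p = 0.266), which lay below the 0.099 to 0.343 of the matched sets.

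Heat shock genes were higher in TMMp plates, at a mean of 2.29 ± 0.25 against 1.41 ± 0.37 on the log2(TPM + 1) scale (SD over 7 and 5 plates, exact permutation p = 0.00253). This difference was not set against matched gene sets. Cluster 4 and mesophyll-like cells, low for these genes, made up 25.3% and 24.8% of ATML1p plates and 5.6% and 0.7% of TMMp plates. Cluster 0, led by heat shock genes, made up 27.4% of TMMp plates and 4.2% of ATML1p plates. Of 53 genes in the test between lines, limma called 2 higher and 1 lower in TMMp. By class the level was 3.73 in TGG1-high guard cell-like cells, 3.18 in FAMA-high guard cell-like cells, 3.15 in cluster 2 and 2.63 in cluster 0. It was 0.87 in mesophyll-like cells and 0.46 in cluster 4, and the other classes lay between 1.5 and 2.22. Within TMMp plates the mean rho with FAMA was 0.219, positive in 7 of 7 plates (exact permutation p = 0.0156, the smallest possible), and lay inside the -0.024 to 0.33 of the matched sets. One hypothesis was that cells held longer after digestion lose RNA and have high heat shock genes, so that the level falls with the number of genes detected. The mean rho with that number was 0.304 (0.161 to 0.466 over plates), but the mean of any gene set rises with genes detected, and the matched sets had 0.471 to 0.871. A loss of RNA and a response that differs between lines or stages may each remain and cannot be told apart here, since the labels give no time or temperature.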
